A study of Homo sapiens with 17 samples.

How the data were processed

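LNCaP is an established human prostate cancer cell line whose growth depends on androgen, and LNCaP-abl (abl below) is a subline of it that grows without androgen. Per the labels, LNCaP was kept in medium with 10% serum and abl in medium with 10% charcoal-stripped serum, which holds little steroid hormone. Cells were split every 2 days and used at passages 32 to 34 for LNCaP and 62 to 64 for abl. For RNA sequencing, each line received a control siRNA (siControl), an siRNA against CREB1 (siCREB1) or an siRNA against FOXA1 (siFOXA1) at 40 nM for 3 days, in medium with 5% charcoal-stripped serum. CREB1 is the cyclic-AMP response element binding protein, and FOXA1 is a pioneer factor that opens chromatin for other transcription factors. The series lists 17 samples. Of these, 6 are RNA samples, each with 2 count columns taken here as 2 libraries, and 3 are chromatin immunoprecipitation (ChIP-seq) samples with a peak list. The other 8 samples are ChIP-seq after knockdown and were not analysed here.

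Raw read counts per gene were deposited, and per the submitters' processing notes they came from CASAVA 1.8, TopHat2 2.0.8, Bowtie2 2.1.0 and HTSeq 0.5.3p9 on hg19. The gene annotation and the strand setting of the counting were not given in the sources used here. Per the labels' protocols the library kit was one that does not mark strand, so overlapping and antisense genes are uncertain. Genes with near-identical copies, such as the UGT2B and HLA families and the BCYRN1 transcript, are uncertain because their reads can map to several copies. The authors' deposited table for each knockdown gives log2 fold changes and p-values, which the submitters' processing notes tie to edgeR 3.0.6. The control columns named SIC were read as siControl. They stand in 3 count tables of each line, and all 8 repeated control columns were identical, so each library was used once. Peak lists with positions and a score per peak were deposited by the authors, and the submitters' processing notes name Bowtie 1.0.0 and MACS 1.4.2 on hg19. Whether libraries were pooled and which input control was used were not given in the sources used here. The authors' score is used only to rank peaks within a list.

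Lines of the count tables that name no gene were left out of library sizes and tests. Reads assigned to no feature made up 54.8% to 58.3% and ambiguous reads 0.77% to 0.92% of the counted total per library. Of 23230 genes, 15550 passed edgeR's filterByExpr. All 12 libraries, in 6 groups of 2, entered 1 fit with edgeR 4.0.16 in R 4.3.3, with TMM scaling and the quasi-likelihood F-test on 6 residual degrees of freedom. The common biological coefficient of variation was 0.062. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene was called changed at an adjusted p below 0.05. Levels are CPM, counts scaled to library size, after TMM scaling, given as mean ± SD of 2 libraries. Log2 fold changes carry a standard error (SE) derived from the test, as the absolute change over the square root of its F statistic. Where a group holds few counts, this SE is only approximate. The difference between the knockdown effects of both lines was tested in the same fit, as was siCREB1 against siFOXA1. For a gene at 0 in every library of a group, the fold is a lower bound against a floor of 3 counts over the group. This bound takes the counts of the other group as exact. For a group with 1 to 3 counts, the ratio carries a 95% counting interval, which covers counting error only.

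A total of 19 gene lists was fixed before the data were examined, as were the tests, the rule for named genes and the alternatives unless a later choice is stated. The lists were androgen response, mitosis, DNA replication, CREB/cAMP-responsive genes, the CREB/ATF family with its co-activators, luminal prostate identity, basal epithelium, neuroendocrine, mesenchymal and migration, cholesterol synthesis, fatty acid synthesis, interferon response, unfolded protein and integrated stress response (stress response below), p53 targets, hypoxia and glycolysis, apoptosis regulators, DNA repair, fibroblast markers, and blood and endothelial markers. Some genes stand in more than 1 list, for example ATF4 in the stress response and CREB/ATF lists. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 19 lists of a comparison. The same test with an estimated correlation and fry were alternatives. Camera compares a list with all other genes, whereas fry asks whether its members move, on balance, one way and compares them with no other genes. Named genes are CREB1, FOXA1, the 6 largest rises and 6 largest falls per comparison (4 for difference tests) among called genes with a mean log2 CPM of at least 3 and libraries that do not overlap between groups, and the 2 called members with the largest change of each list with at least 3 called members. Some genes that this rule takes are not reported here.

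Peaks sharing at least 1 bp were counted as overlapping, with 95% Wilson intervals. These intervals treat peaks as independent and cover peak counting only, not the spread between experiments. Chance overlap was the mean of 100 random shifts of each peak by 20 to 200 kb, computed in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. No hg19 gene annotation was used here, so peaks were not assigned to genes. Figures were drawn with matplotlib 3.10.9.

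Depth was 9092597 to 37314039 reads in genes per library. The fit was tested on simulated counts with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. These were drawn from genes with a mean log2 CPM of at least 1, so recovery does not cover genes with fewer counts. Far fewer genes changed than in the data, where 37.6% to 63.6% of tested genes were called in these 5 comparisons. For siCREB1 in abl it recovered 77.6%, 89.6% and 97% of them and also called 16 unchanged genes, with 15420 genes in the fit. The corresponding values were 73.1%, 95.5% and 98.5% with 14 unchanged genes called and 15390 in the fit for siFOXA1 in abl, and 79.1%, 100% and 100% with 8 and 15422 for siCREB1 in LNCaP. They were 77.6%, 97% and 97% with 10 and 15369 for siFOXA1 in LNCaP, and 91%, 92.5% and 98.5% with 14 and 15358 for abl against LNCaP. Libraries of a group differed beyond sampling noise, with a chi-square per gene of 4.85 to 11.7 over genes with at least 100 counts. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

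Alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, a stricter one at a mean log2 CPM of 1, the replicate number as a block, only the groups compared, each library left out in turn, an adjusted p below 0.01, and other overlap rules for peaks. Leaving out both first siControl libraries was added after the data were seen. White blood cell markers were listed after the main results were seen. Before this list was tested, an effect of the control siRNA was held to the level of the second siControl library, over all markers, against 2 times that of the knockdown libraries. Over the markers near 0 under the knockdowns, chosen after the result was seen, it was held to a ratio of the first to the second siControl library above 5, which was not met. That later bound was replaced, again after the values were seen, by a 95% counting limit above 1 and by 10000 gene sets drawn with matched siControl counts.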

Results

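RNA was sequenced from LNCaP and LNCaP-abl (abl) prostate cancer cells treated with a control siRNA, an siRNA against CREB1 or an siRNA against FOXA1, with 2 libraries in each of the 6 groups. Reads assigned to genes per library were 27555950 and 15200856 for LNCaP siControl, 25700956 and 26428435 for LNCaP siCREB1, and 22655155 and 25219041 for LNCaP siFOXA1. In abl they were 37314039 and 9092597 for siControl, 22916312 and 25437588 for siCREB1, and 22943180 and 24176310 for siFOXA1. CREB1 binding was mapped by ChIP-seq in both lines and FOXA1 binding in abl, with 1 peak list each. In the first siControl library of both lines, 6 genes chosen after their values were seen had at least 11 counts, against at most 2 in every other library. They include CSF3R, a receptor of neutrophils, with 76 counts in LNCaP and 87 in abl, and S100A8, a neutrophil calcium-binding protein, with 20 counts in each.

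The targeted genes came first. CREB1 in LNCaP stood at 81.0 and 85.3 CPM in the siControl libraries, 38.7 and 29.8 in the siCREB1 libraries and 61.4 and 60.7 in the siFOXA1 libraries. In abl CREB1 stood at 78.8 and 79.7, then 46.3 and 43.9, then 60.4 and 56.1 CPM. The siCREB1 group thus kept 41.2% of the siControl level in LNCaP and 56.9% in abl. FOXA1 in LNCaP stood at 798.8 and 695.4 CPM under siControl, 655.1 and 658.2 under siCREB1, and 215.1 and 210.8 under siFOXA1. In abl FOXA1 stood at 556.4 and 504.1, then 529.5 and 547.2, then 195.6 and 229.1 CPM. The siFOXA1 group kept 28.5% of the siControl level in LNCaP and 40% in abl. In edgeR's quasi-likelihood test CREB1 fell by 1.28 ± 0.10 on the log2 scale under siCREB1 in LNCaP (SE, Benjamini-Hochberg adjusted p = 5.59e-07) and by 0.81 ± 0.10 in abl (adjusted p = 9.1e-06). CREB1 also fell under siFOXA1, by 0.44 ± 0.09 in LNCaP (edgeR adjusted p = 0.00126) and by 0.44 ± 0.09 in abl (adjusted p = 0.00114). FOXA1 fell under siFOXA1 by 1.81 ± 0.09 in LNCaP (edgeR adjusted p = 2.15e-09) and by 1.32 ± 0.08 in abl (adjusted p = 2.04e-08). The log2 change of FOXA1 under siCREB1 was -0.19 ± 0.08 in LNCaP (edgeR adjusted p = 0.0913) and 0.02 ± 0.08 in abl (adjusted p = 0.864). Without the second LNCaP siControl library the LNCaP value was -0.28 and passed (adjusted p = 0.0265). Without the second abl siControl library the abl value was -0.05.

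**Figure D1:**
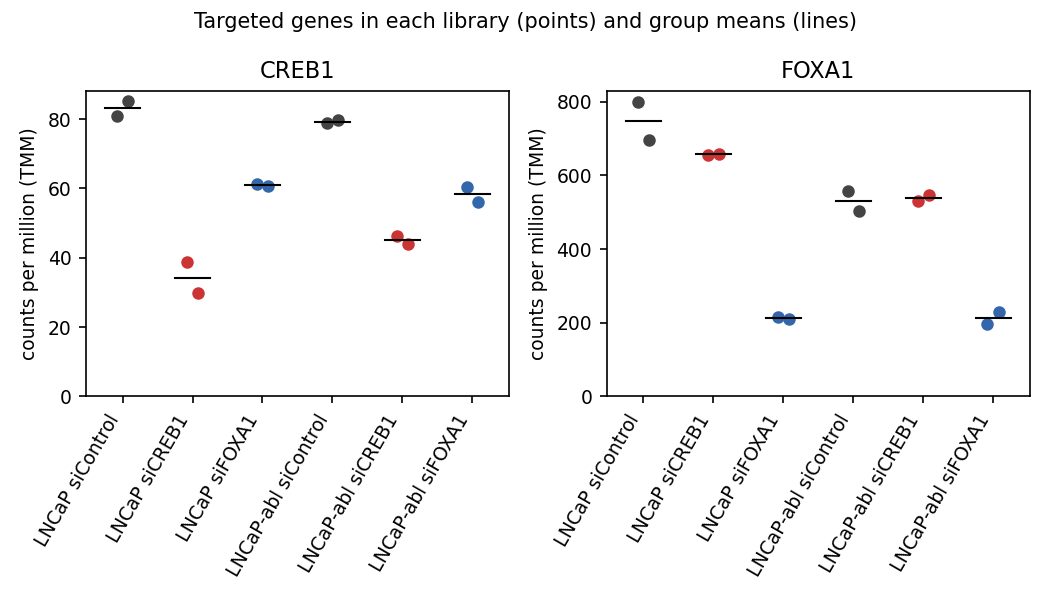
TMM-scaled CPM of CREB1 and FOXA1 in each of the 12 libraries (points) and group means (lines), by cell line and siRNA. CREB1 was lowest under siCREB1 and FOXA1 under siFOXA1 in both lines.

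The first comparison asked how the androgen-independent abl line responded to siCREB1. Genes of the amino acid and protein folding stress response fell (camera adjusted p = 0.00839 with an estimated correlation). Mitosis genes fell as well, and cholesterol synthesis and most measured androgen response genes were higher, but none of these lists passed camera with an estimated correlation (adjusted p = 0.56, 0.716 and 0.716). The stress genes CHAC1, which degrades glutathione, and SESN2, a stress-induced sestrin, fell by 3.56 ± 0.11 and 2.49 ± 0.10 on the log2 scale. CHAC1 went from 179 ± 2.25 to 15.2 ± 2.71 CPM (SD, n = 2). VEGFA, a vascular growth factor, fell from 390 ± 35.8 to 88.2 ± 3.05 CPM, and FASN, the fatty acid synthase, rose from 1160 ± 239 to 3987 ± 1182 CPM.

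Among the largest falls in abl under siCREB1, the calcium-binding protein S100P fell by 6.05 ± 0.21 on the log2 scale, from 53.1 ± 6.72 to 0.786 ± 0.0917 CPM (edgeR adjusted p = 1.87e-10). ADM2, a peptide hormone of the calcitonin family, fell by 3.60 ± 0.08, FAM129A by 3.43 ± 0.10 and LOC100505633 by 3.97 ± 0.18. The cystine transporter SLC7A11 fell by 3.38 ± 0.14, from 1045 ± 109 to 101 ± 19.4 CPM. The largest rises included BCYRN1, a short noncoding RNA with near-identical copies, at 2.79 ± 0.16. ABAT, which breaks down the transmitter GABA, rose by 2.41 ± 0.14, and ALDH1A3, a retinaldehyde dehydrogenase, by 2.13 ± 0.16. ID1 and ID3, inhibitors of helix-loop-helix factors, rose by 2.57 ± 0.44 and 2.44 ± 0.39. The BMP receptor gene BMPR1B rose by 2.50 ± 0.65 over 2 counts in the siControl group (fitted ratio 5.67, 95% counting interval 1.73 to 51.5). BMPR1B was at 1.28 (edgeR adjusted p = 0.437) without the first siControl library and 2.32 (adjusted p = 0.0528) without the first siCREB1 library.

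Of 22 stress response genes, 21 fell and 0 rose, and the same adjusted over the list alone. Its median log2 change was -1.28 (camera adjusted p = 1.2e-41, and adjusted p = 0.00839 with an estimated correlation). Of the mitosis genes, 32 of 34 fell (32 adjusted over the list alone), such as the kinetochore gene CENPF by 2.04 ± 0.14 and the kinesin KIF2C by 2.03 ± 0.16. That list had a median of -1.16 (camera adjusted p = 6.73e-15, adjusted p = 0.56 with an estimated correlation). In the CREB/ATF family, which contains CREB1 itself, 15 of 21 members fell and 4 rose, with the same counts adjusted over the list alone. ATF6, a sensor of protein folding stress, fell by 1.56 ± 0.07 and CREB5 rose by 1.38 ± 0.28. The family's median was -0.48 (camera adjusted p = 1.02e-05, adjusted p = 0.0181 with an estimated correlation).

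Cholesterol synthesis genes were higher for 15 of 24 members and lower for 2 (15 and 2 adjusted over the list alone), for example MVD by 1.14 ± 0.10. The list had a median of 0.40 (camera adjusted p = 0.00213, adjusted p = 0.716 with an estimated correlation). DNA replication genes went up for 20 of 38 members and down for 3 (21 and 3 adjusted over the list alone), with GINS2 at 1.52 ± 0.22 and UHRF1 at 1.42 ± 0.13. Their median was 0.37 (camera adjusted p = 0.0232, adjusted p = 0.919 with an estimated correlation). Of 32 androgen response genes, 18 rose and 5 fell (19 and 5 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.025, adjusted p = 0.716 with an estimated correlation).

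The other 13 lists did not pass camera in abl under siCREB1. Members rose and fell in the CREB/cAMP-responsive list (10 and 9 of 32), where PCK2, a gluconeogenic enzyme, fell by 2.85 ± 0.07, and in hypoxia and glycolysis (11 and 8 of 23). The same held for apoptosis regulators (10 and 11 of 25), where the survival gene BCL2 fell by 1.36 ± 0.16, and for p53 targets (6 and 8 of 21), where BTG2 rose by 1.37 ± 0.17. Luminal identity had 9 higher and 5 lower of 18, with the splicing regulator ESRP1 falling by 1.74 ± 0.08. Fatty acid synthesis had 9 and 4 of 18, neuroendocrine genes 5 and 4 of 13, mesenchymal genes 3 and 6 of 17 and DNA repair 3 and 9 of 30. Thrombospondin THBS1 of the mesenchymal list fell by 3.00 ± 0.21, and the repair gene BRCA2 by 1.26 ± 0.18. Fibroblast markers had 2 higher and 0 lower of 6, and blood and endothelial markers 1 and 1 of 5. All these counts were the same adjusted over the list alone. Basal genes had 1 higher and 2 lower of 9 (0 and 2 adjusted over the list alone), with a median of 0.12 (0 with genes at 0 set to their bounds) whose camera direction was downward. Interferon genes had 5 higher and 0 lower of 26 (1 and 0 adjusted over the list alone).

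In all, 7962 of 15550 genes passed edgeR's test at a Benjamini-Hochberg adjusted p below 0.05 in abl under siCREB1, 4282 higher and 3680 lower. Of these, 616 were higher and 772 lower by at least 1 on the log2 scale. In the authors' deposited table for this comparison, 7940 listed genes were among those tested here, all with the same sign, and 95.8% of them were called here. A further 355 genes called here were not listed by the authors.

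**Figure D2:**
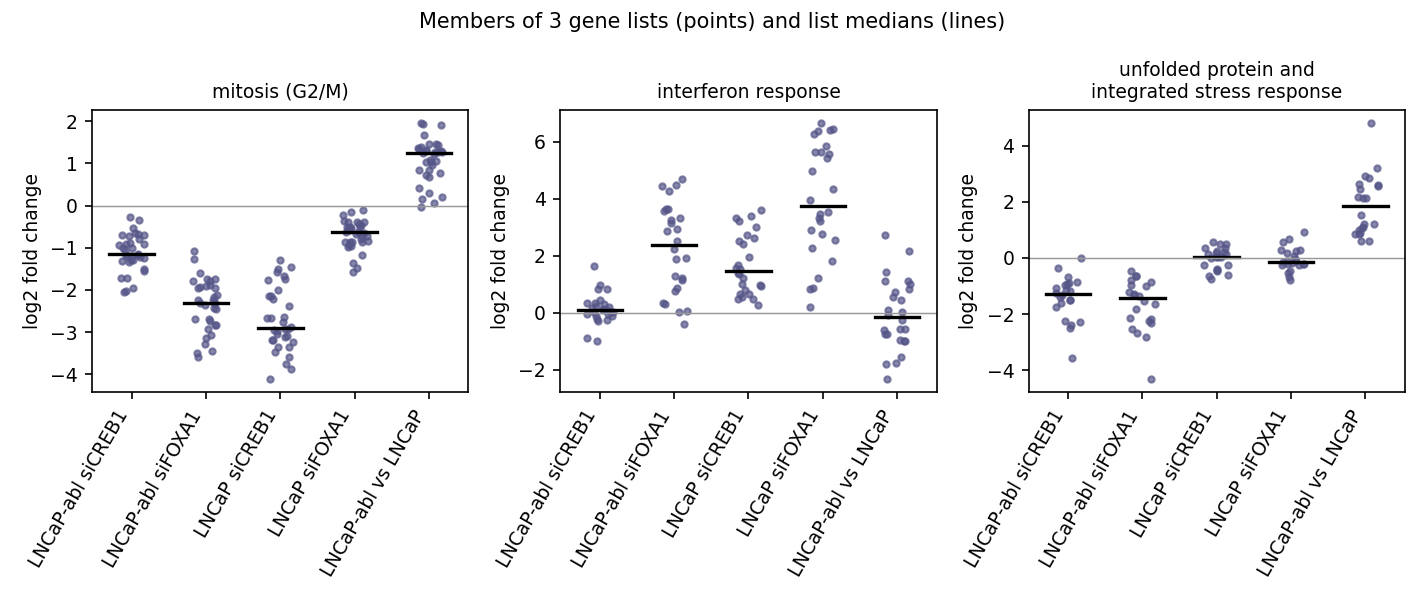
Log2 fold changes of the members (points) of the mitosis, interferon response and stress response lists, with list medians (lines), for the 4 knockdown comparisons and for abl against LNCaP under siControl. Mitosis medians lay between -0.63 and -2.90 under the knockdowns, and stress response medians were -1.28 and -1.44 in abl.

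Under siFOXA1 in abl, genes of the interferon response rose and genes of mitosis and of the stress response fell. With an estimated correlation camera passed the stress response (adjusted p = 0.0127) but not the interferon response (0.377) or mitosis (0.119). ABP1, the diamine oxidase gene, rose from 6.56 ± 1.25 to 517 ± 32.9 CPM (SD, n = 2), and the death-associated kinase DAPK1 from 4.08 ± 0.0673 to 89.8 ± 14.4 CPM. The interferon-induced gene IFI27 rose by 4.48 ± 0.36 on the log2 scale. Every one of the 34 measured mitosis genes and of the 22 measured stress response genes fell. ATF4, the central transcription factor of the integrated stress response, went from 1321 ± 22.2 to 378 ± 6.85 CPM.

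ABP1 rose by 6.21 ± 0.14 on the log2 scale (edgeR adjusted p = 1.9e-12) and DAPK1 by 4.47 ± 0.13 (adjusted p = 1.82e-11). The other largest rises were BST2 at 4.65 ± 0.38 and OAS2 at 4.27 ± 0.53, both interferon-induced antiviral genes, and the nuclease gene DNASE1L3 at 4.29 ± 0.25. S100P fell by 6.61 ± 0.23, from 53.1 ± 6.72 to 0.542 ± 0.339 CPM (edgeR adjusted p = 6.55e-11), LRRC31 by 4.87 ± 0.20 and THBS1 by 4.71 ± 0.26. ADM2 fell by 4.61 ± 0.08 and the neutral amino acid transporter SLC1A4 by 4.52 ± 0.15. MSN, which links the membrane to actin, was called lower at -4.73 ± 0.97 over 1 count in the siFOXA1 group (fitted ratio 26.5, 95% counting interval 5.91 to 1302). Without the first siControl library MSN was at -2.06 (edgeR adjusted p = 0.414), and without the first siFOXA1 library at a fitted -7.13, which is no bound since 0 counts then remain in that group.

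All 34 mitosis genes fell (34 adjusted over the list alone), among them CENPF by 3.59 ± 0.16 and KIF2C by 3.50 ± 0.18. The median was -2.30 (camera adjusted p = 1.97e-37, adjusted p = 0.119 with an estimated correlation). All 22 stress response genes fell (22 adjusted over the list alone), with CHAC1 down by 4.32 ± 0.12 and the serine synthesis enzyme PSAT1 by 2.81 ± 0.07. Their median was -1.44 (camera adjusted p = 9.87e-40, adjusted p = 0.0127 with an estimated correlation). In the CREB/ATF family 15 of 21 members fell and 3 rose, the same adjusted over the list alone, with ATF4 falling by 1.81 ± 0.06 and CREB3L2 by 1.5 ± 0.08. Its median was -0.44 (camera adjusted p = 0.000149, adjusted p = 0.0365 with an estimated correlation).

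Interferon genes rose for 22 of 26 members and fell for 1 (23 and 1 adjusted over the list alone), with a median of 2.37 (camera adjusted p = 1.98e-07, adjusted p = 0.377 with an estimated correlation). DNA replication genes fell for 26 of 38 and rose for 2 (27 and 2 adjusted over the list alone), with the polymerase POLE down by 2.08 ± 0.09. That median was -0.54 (camera adjusted p = 0.00121, adjusted p = 0.377 with an estimated correlation). DNA repair had 17 of 30 members lower and 3 higher, the same adjusted over the list alone, with BRCA2 down by 2.25 ± 0.21 and a median of -0.31 (camera adjusted p = 0.00961, adjusted p = 0.377 with an estimated correlation). Cholesterol synthesis had 16 higher and 2 lower of 24 (17 and 2 adjusted over the list alone) and a median of 0.40 (camera adjusted p = 0.0012, adjusted p = 0.377 with an estimated correlation). Hypoxia and glycolysis had 16 higher and 4 lower of 23, the same adjusted over the list alone. The glycolytic enzyme ALDOC was up by 1.22 ± 0.08 and VEGFA down by 2.00 ± 0.11, and the median was 0.50 (camera adjusted p = 0.0035, adjusted p = 0.168 with an estimated correlation).

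The other 11 lists did not pass camera in abl under siFOXA1. Androgen response genes were 10 higher and 13 lower of 32, the latter including SLC45A3 by 2.37 ± 0.19 and the ETS factor SPDEF by 2.25 ± 0.13. Luminal identity had 5 higher and 7 lower of 18, with keratin KRT19 rising by 3.19 ± 0.35. The CREB/cAMP-responsive list had 9 and 10 of 32, with the kinase SGK1 rising by 2.72 ± 0.27, and fatty acid synthesis 10 and 7 of 18, with ELOVL7 rising by 1.51 ± 0.10. Mesenchymal genes had 8 and 4 of 17, neuroendocrine genes 5 and 3 of 13, fibroblast markers 2 and 0 of 6, and blood and endothelial markers 1 and 2 of 5. These counts were the same adjusted over the list alone. CALCA, the calcitonin gene, fell by 4.80 ± 0.59. Counts differed slightly adjusted over the list alone for basal genes (4 higher and 1 lower of 9, against 3 and 1) and p53 targets (11 and 2 of 21, against 11 and 4). They also differed for apoptosis regulators (9 and 6 of 25, against 10 and 8), where the death-promoting gene BCL2L11 rose by 1.81 ± 0.09. The basal median of 1.4 became 0.42 with genes at 0 set to their bounds.

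In all, 8779 genes passed in abl under siFOXA1, 4651 higher and 4128 lower, with 1028 higher and 1104 lower by at least 1 on the log2 scale. Of 8594 tested genes in the authors' deposited table, all had the same sign and 96.9% were called here. A further 450 genes called here were not listed by the authors.

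In LNCaP under siCREB1, genes of cell division fell and interferon-induced genes rose. With an estimated correlation camera passed mitosis (adjusted p = 0.0387) but not the interferon response (0.143). The topoisomerase TOP2A fell from 48.4 ± 1.37 to 3.28 ± 0.989 CPM (SD, n = 2), and the microtubule-associated DLGAP5 from 18.3 ± 0.735 to 1.04 ± 0.589. IFIT1, which binds viral RNA, rose from 3.95 ± 1.51 to 38.8 ± 4.95 CPM. KLK3, which encodes prostate-specific antigen, fell from 72.2 ± 2.38 to 21.5 ± 7.74 CPM.

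TOP2A fell by 3.88 ± 0.19 on the log2 scale (edgeR adjusted p = 1.41e-08) and DLGAP5 by 4.12 ± 0.26 (adjusted p = 1.27e-07). IQGAP3, CASC5 and HMMR, which act in dividing cells, fell by 3.80 ± 0.17, 3.76 ± 0.29 and 3.75 ± 0.24. DENND2D had 0 counts under siCREB1 and 3 in each siControl library (edgeR adjusted p = 0.0138). It was at least 2.73-fold lower only if these few siControl counts are taken as exact. Its adjusted p was 0.0527 without the second siControl library, and 0.0613 and 0.0624 without the first and second siCREB1 libraries. IFIT1 rose by 3.21 ± 0.34 (edgeR adjusted p = 1.04e-05), and the antiviral genes OAS2, RSAD2 and OASL by 3.60 ± 0.48, 3.40 ± 0.63 and 3.00 ± 0.58. ID3 rose by 4.18 ± 0.55, from 1.68 ± 0.839 to 33.3 ± 15.5 CPM. ID1 was called higher at 4.35 ± 1.04 (edgeR adjusted p = 0.00498), but was at 3.33 (adjusted p = 0.0582) without the first siCREB1 library.

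All 34 mitosis genes fell (34 adjusted over the list alone), with a median of -2.90 (camera adjusted p = 3.23e-94, and adjusted p = 0.0387 with an estimated correlation). DNA replication genes fell for 29 of 38 members and rose for 0 (29 and 1 adjusted over the list alone), with the replication initiator MCM10 down by 3.85 ± 0.29 and the ribonucleotide reductase RRM2 by 3.01 ± 0.23. Their median was -0.55 (camera adjusted p = 1.1e-11, adjusted p = 0.143 with an estimated correlation). DNA repair genes fell for 19 of 30 and rose for 1 (21 and 3 adjusted over the list alone), with BRCA2 down by 2.59 ± 0.22. The repair median was -0.41 (camera adjusted p = 1.95e-06, adjusted p = 0.143 with an estimated correlation). Interferon genes rose for 24 of 26 members and fell for 0 (24 and 0 adjusted over the list alone), with a median of 1.45 (camera adjusted p = 9.68e-19, adjusted p = 0.143 with an estimated correlation).

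Cholesterol synthesis had 12 higher and 0 lower of 24 (13 and 0 adjusted over the list alone), for example DHCR7 by 0.65 ± 0.09, and a median of 0.22 (camera adjusted p = 0.00053, adjusted p = 0.411 with an estimated correlation). Hypoxia and glycolysis had 6 higher and 8 lower of 23, the same adjusted over the list alone, with the glycolytic enzyme PGAM1 down by 1.52 ± 0.06. That median was -0.09 (camera adjusted p = 0.0301, adjusted p = 0.246 with an estimated correlation). Neuroendocrine genes had 0 higher and 2 lower of 13, the same adjusted over the list alone. Their median was -0.35, or -0.20 with genes at 0 set to their bounds (camera adjusted p = 0.0429, adjusted p = 0.143 with an estimated correlation). With the replicate number as a block, camera's adjusted p for the neuroendocrine list was 0.0561.

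Of the 12 lists that did not pass camera in LNCaP under siCREB1, androgen response genes had 8 higher and 7 lower of 32, with KLK3 falling by 1.74 ± 0.19 and the acid phosphatase ACPP by 1.28 ± 0.13. The stress response list had 6 higher and 8 lower of 22 and a median of 0.03 (camera adjusted p = 0.742), with the stress factor XBP1 falling by 0.74 ± 0.06. The CREB/ATF family had 3 and 9 of 21, with ATF2 falling by 0.65 ± 0.07, and the CREB/cAMP-responsive list 6 and 4 of 32. Fatty acid synthesis had 6 and 2 of 18, p53 targets 4 and 5 of 21, mesenchymal genes 2 and 5 of 17 and basal genes 1 and 3 of 9. The receptor TGFBR1 of the mesenchymal list fell by 1.67 ± 0.09. Fibroblast markers had 2 and 1 of 6, and blood and endothelial markers 0 and 1 of 5. All these counts were the same adjusted over the list alone. Luminal identity had 6 and 3 of 18 (6 and 5 adjusted over the list alone), and apoptosis regulators 8 and 4 of 25 (8 and 5 adjusted over the list alone), with PMAIP1 rising by 1.09 ± 0.19.

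In all, 5846 genes passed in LNCaP under siCREB1, 2770 higher and 3076 lower, with 202 higher and 434 lower by at least 1 on the log2 scale. Which direction had more genes depended on the scaling, since RLE gave 2989 higher and 2854 lower and DESeq2 2500 and 2403. Of 4570 tested genes in the authors' deposited table, all had the same sign and 97.4% were called here. A further 1394 genes called here were not listed by the authors, and a fit of only the groups compared called 4456 genes.

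Under siFOXA1 in LNCaP, interferon-induced genes, p53 targets and most tested basal epithelial genes rose. None of these lists passed camera with an estimated correlation (adjusted p = 0.104, 0.484 and 0.149). DAPK1 rose from 0.964 ± 0.0864 to 354 ± 13.4 CPM (SD, n = 2), and the antiviral gene IFIT3 from 3.22 ± 0.2 to 187 ± 5.58 CPM. CDKN1A, the p53-induced cell cycle inhibitor p21, rose from 127 ± 7.94 to 414 ± 15.2 CPM. ACPP, which encodes prostatic acid phosphatase, fell from 507 ± 9.37 to 24.6 ± 2.84 CPM. THBS1, which fell in abl, rose here from 26.9 ± 2.76 to 580 ± 130 CPM.

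DAPK1 rose by 8.54 ± 0.16 on the log2 scale (edgeR adjusted p = 4.49e-13), OAS2 by 6.66 ± 0.38, OASL by 6.43 ± 0.52 and RSAD2 by 6.38 ± 0.53. IFIT3 rose by 5.85 ± 0.47 and the signalling adaptor GAB3 by 5.65 ± 0.18. ACPP fell by 4.36 ± 0.15 (edgeR adjusted p = 1.37e-10), the hormone gene RLN1 fell by 4.92 ± 0.21 and LOC145837 by 5.01 ± 0.29. The odorant receptor OR51E1, found in prostate, fell by 4.60 ± 0.28. DAB1 was lower at -4.77 ± 0.47 over 3 counts in the siFOXA1 group (fitted ratio 27.3, 95% counting interval 10.1 to 143), and at a fitted -8.37, which is no bound, without the second siFOXA1 library, when 0 counts remain.

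All 26 interferon genes rose (26 adjusted over the list alone), with a median of 3.74 (camera adjusted p = 7.48e-44, adjusted p = 0.104 with an estimated correlation). Of 21 p53 targets, 18 rose and 2 fell (19 and 2 adjusted over the list alone), with CDKN1A up by 1.70 ± 0.26 and the death receptor FAS by 1.86 ± 0.16. The median was 0.77 (camera adjusted p = 1.22e-05, adjusted p = 0.484 with an estimated correlation). Basal genes rose for 7 of 9 tested members and fell for 1, the same adjusted over the list alone. The basal markers KRT5, KRT15 and TP63 of the fixed list were not among the tested genes. The hemidesmosome collagen COL17A1 was up by 5.55 ± 0.28, and keratin KRT17 by 6.26 ± 0.63 over 1 count in the siControl group (fitted ratio 76.9, 95% counting interval 16.8 to 3704). The median of the tested basal genes was 2.26 (camera adjusted p = 0.00171, adjusted p = 0.149 with an estimated correlation).

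Mitosis genes fell for 27 of 34 members and rose for 0 (28 and 0 adjusted over the list alone), with the proliferation marker MKI67 down by 1.58 ± 0.19. Their median was -0.63 (camera adjusted p = 1.22e-05, adjusted p = 0.491 with an estimated correlation). Androgen response genes fell for 16 of 32 and rose for 9, the same adjusted over the list alone, with the steroid-conjugating UGT2B17 down by 5.01 ± 0.95. That median was -0.34 (camera adjusted p = 0.0241, adjusted p = 0.491 with an estimated correlation). Fatty acid synthesis fell for 9 of 18 and rose for 5 (10 and 5 adjusted over the list alone), with the desaturase FADS2 down by 1.45 ± 0.10 and a median of -0.60 (camera adjusted p = 0.0318, adjusted p = 0.484 with an estimated correlation).

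The other 13 lists did not pass camera in LNCaP under siFOXA1. The stress response list had 5 higher and 9 lower of 22 and a median of -0.14 (camera adjusted p = 0.54). Luminal identity had 8 and 7 of 18, with SPDEF falling by 2.29 ± 0.13, the CREB/ATF family 4 and 10 of 21, and DNA replication 2 and 9 of 38. Mesenchymal genes had 6 and 3 of 17, with THBS1 up by 4.42 ± 0.15 and SNAI2, a repressor of epithelial genes, by 3.84 ± 0.54. Hypoxia and glycolysis had 12 and 3 of 23, with ERO1L up by 1.51 ± 0.08, apoptosis regulators 10 and 4 of 25, and DNA repair 3 and 7 of 30, with RAD54B up by 1.86 ± 0.13. Neuroendocrine genes had 1 and 5 of 13, fibroblast markers 2 and 2 of 6, and blood and endothelial markers 1 and 3 of 5, with VWF falling by 3.55 ± 0.23. These counts were the same adjusted over the list alone. Cholesterol synthesis had 4 and 6 of 24 (3 and 5 adjusted over the list alone), and the CREB/cAMP-responsive list 10 and 9 of 32 (11 and 10 adjusted over the list alone), with SGK1 up by 4.09 ± 0.27.

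In all, 7748 genes passed in LNCaP under siFOXA1, 3787 higher and 3961 lower, with 802 higher and 866 lower by at least 1 on the log2 scale. The balance was 3594 higher and 3544 lower with a stricter filter on low counts. Of 6681 tested genes in the authors' deposited table, all had the same sign and 98.6% were called here. A further 1158 genes called here were not listed by the authors, and a fit of only the groups compared called 6819 genes. Beside the camera calls named above, fry found lists moving on balance one way in 9, 13, 12 and 12 of the 19 lists for siCREB1 and siFOXA1 in abl and siCREB1 and siFOXA1 in LNCaP. With an estimated correlation, the calls that held were the stress response and CREB/ATF lists in abl under both knockdowns and mitosis in LNCaP under siCREB1.

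**Figure D3:**
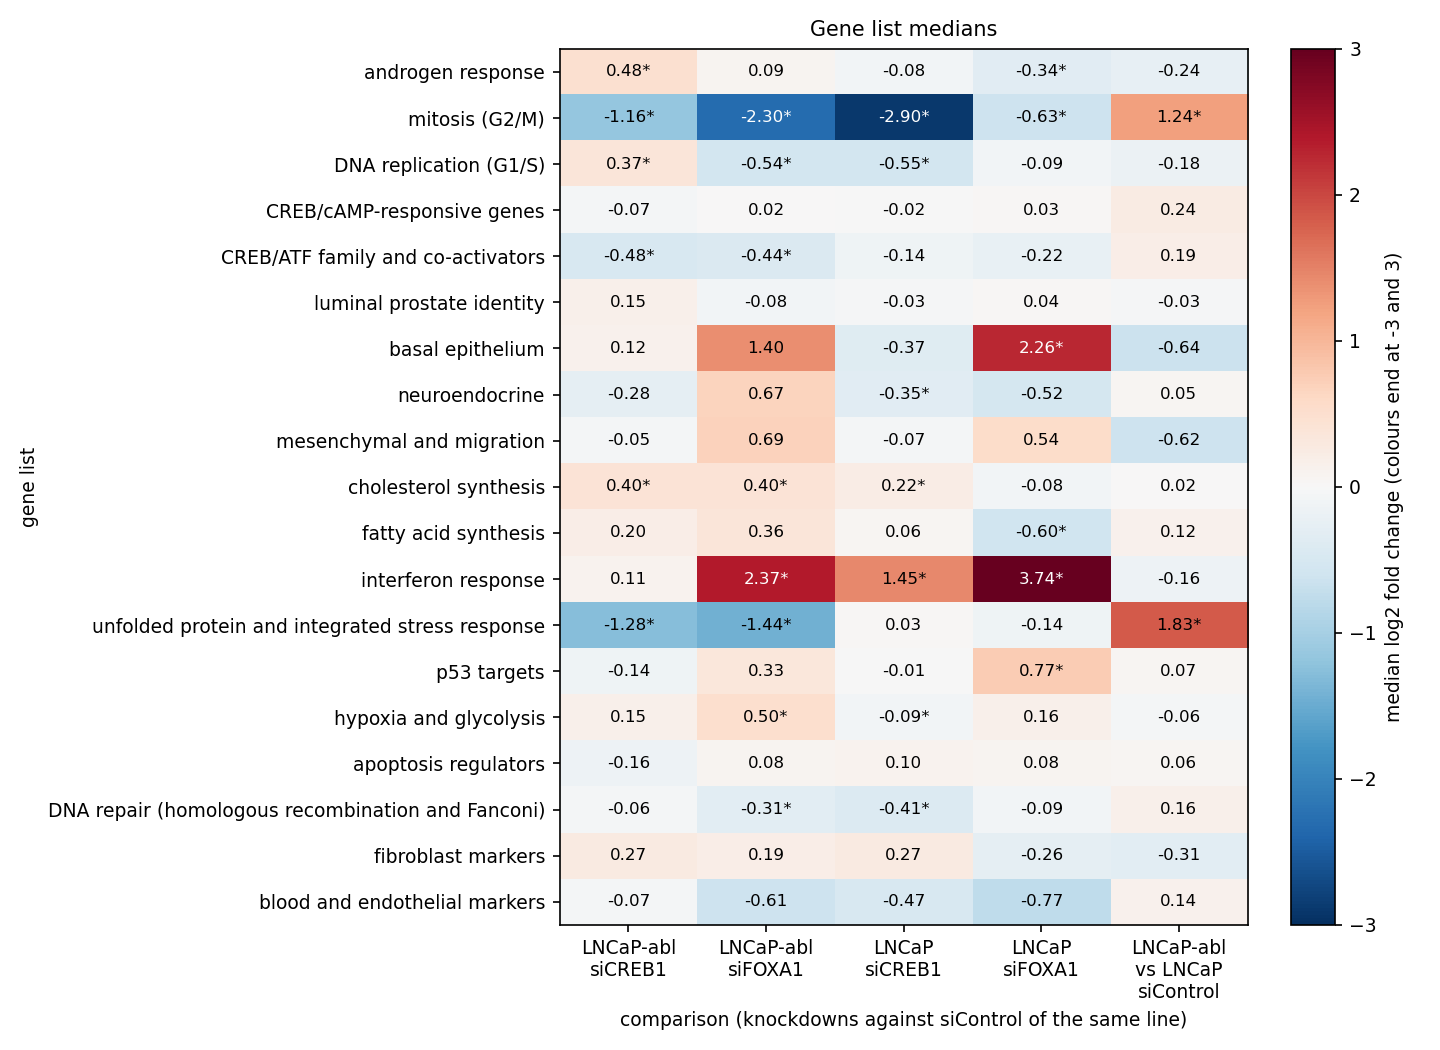
Median log2 fold change of the 19 gene lists in the 4 knockdown comparisons and in abl against LNCaP under siControl, with an asterisk where camera's adjusted p at the preset correlation was below 0.05. The interferon median of 3.74 in LNCaP under siFOXA1 was the highest, and the mitosis median of -2.90 in LNCaP under siCREB1 the lowest.

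The next comparison asked how far both knockdowns moved the same genes within a line. In abl, 2940 genes were higher and 2560 lower under both, against 1281 and 977 for independent lists of the same sizes, and 501 moved in opposite directions. In LNCaP, 1572 were higher and 1766 lower under both, against 675 and 784, and 570 moved in opposite directions. ID1 and AKR1C3, an enzyme of androgen synthesis, were higher in all 4 knockdown comparisons and SLC7A5, a transporter of large amino acids, lower, all chosen after their values were seen. AKR1C3 stood at 1.96 and 3.31 under siCREB1 and siFOXA1 in abl, and at 2.1 and 3.19 in LNCaP. SLC7A5 stood at -2.16, -2.74, -1.25 and -1.47 in the same order. The 4 comparisons shared 918 higher and 945 lower genes. Comparisons within a line share siControl libraries, and no value expected by chance was computed for these counts. The lower genes include G0S2, CSF3R and SRGN, whose siControl counts lie almost only in the first library of each line. The call of ID1 in LNCaP under siCREB1 was lost without the first siCREB1 library (log2 change 3.33).

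Both knockdowns were set against the same siControl libraries. Across genes, which are not independent replicates, their log2 fold changes correlated at 0.64 in abl and 0.43 in LNCaP. Simulated unchanged groups against the same controls gave mean correlations of 0.52 and 0.55 over 20 draws, with a mean of at most 0.15 genes shared in a direction. The observed covariance was 0.471 in abl and 0.242 in LNCaP, against 0.058 and 0.05 simulated, a difference of 0.413 and 0.192. Controls could not be split with 2 libraries in each part, so part of the excess overlap may come from the shared controls.

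**Figure D4:**
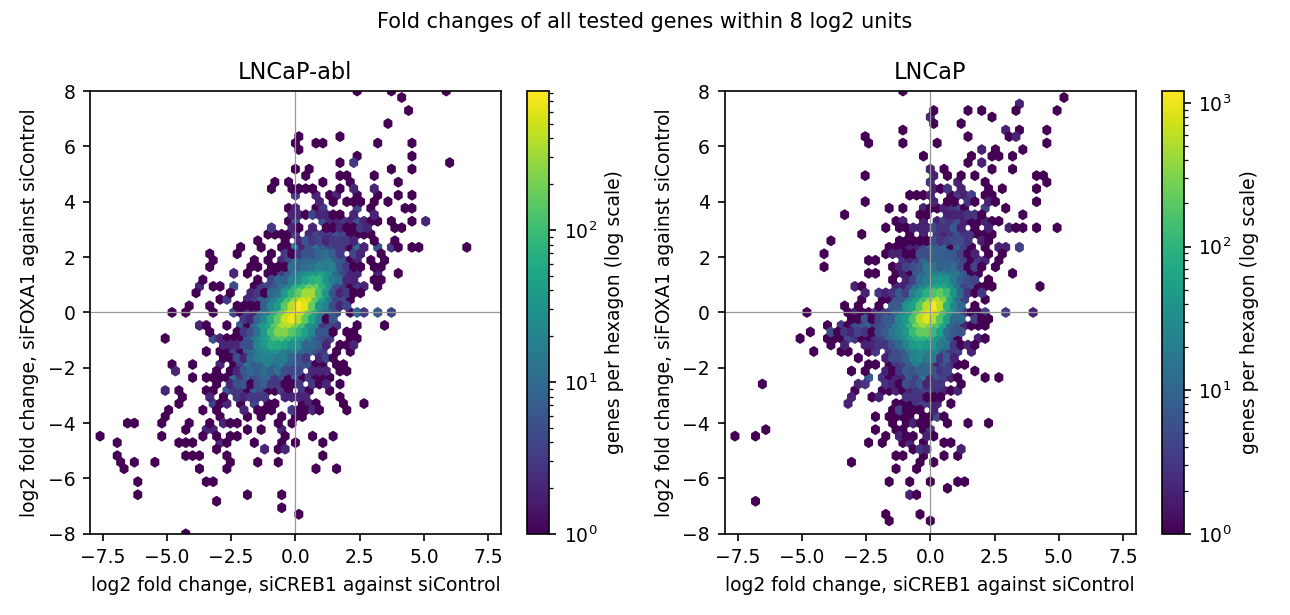
Log2 fold changes of siFOXA1 (vertical axis) against those of siCREB1 (horizontal axis), each against siControl, for tested genes within 8 log2 units in abl (left) and LNCaP (right), with colour giving genes per hexagon on a log scale. The correlation across genes was 0.64 in abl and 0.43 in LNCaP.

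Set directly against each other, siCREB1 and siFOXA1 differed in both lines. In abl, LRRC31 stood at 22.6 ± 3.57 CPM under siCREB1 and 1.05 ± 0.267 under siFOXA1 (SD, n = 2, edgeR adjusted p = 3.71e-09). LRRC31, TGM3 and TMEFF2 were higher under siCREB1 by 4.42 ± 0.20, 4.02 ± 0.25 and 3.80 ± 0.28. ABP1, IFI27 and BST2 were lower under siCREB1, at -5.23 ± 0.12, -5.46 ± 0.40 and -4.92 ± 0.37. DIRAS1 had 0 counts under siCREB1 and 4 under siFOXA1, too few for a fold (edgeR adjusted p = 0.0495). It was not called without the first or second siCREB1 library or the first siFOXA1 library. Its call was also lost with the replicate number as a block (adjusted p = 0.0596), RLE scaling (0.0531), no low-count filter (0.0529) and DESeq2 (0.0794). Mitosis genes were higher under siCREB1 for 34 of 34 members (median 1.30) and interferon genes lower for 21 of 26 (median -2.12).

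In LNCaP, RLN1 was higher under siCREB1 than under siFOXA1 by 4.61 ± 0.21, as was LOC145837 by 4.75 ± 0.30. DAPK1, the chemokine gene CCL5 and THBS1 were lower, at -9.32 ± 0.16, -4.75 ± 0.29 and -4.20 ± 0.15 (edgeR adjusted p = 2.17e-13, 2.46e-08 and 1.5e-10). Mitosis genes were lower under siCREB1 for 34 of 34 members (median -2.13) and interferon genes for 24 of 26 (median -2.21). In all, 6368 genes differed in abl (3107 higher under siCREB1 and 3261 lower, or 3419 and 3256 in a fit of only the groups compared) and 6691 in LNCaP (3200 and 3491, or 3349 and 3340 with RLE scaling). In these direct comparisons camera called 8 lists in abl and 11 in LNCaP, and 0 of either with an estimated correlation, whereas fry called 13 and 14.

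The last expression comparison set abl against LNCaP, both under siControl, which asks how the androgen-independent line differs from its parent. Genes of the stress response and of mitosis were higher in abl, with camera adjusted p = 0.0364 and 0.975 with an estimated correlation. KLK3 was nearly absent, at 0.236 ± 0.177 CPM against 72.2 ± 2.38 in LNCaP (SD, n = 2). BCAT1, which degrades branched-chain amino acids, stood at 215 ± 6.34 against 0.549 ± 0.143 CPM. The ETS factor ETV1 stood at 0.209 ± 0.137 against 454 ± 26.3 CPM. ATF4 was higher in abl by 2.44 ± 0.06 on the log2 scale (edgeR adjusted p = 4.44e-13).

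No difference in CREB1 between the lines passed the test (-0.07 ± 0.09, edgeR adjusted p = 0.541), whereas FOXA1 was lower in abl at -0.49 ± 0.08 (adjusted p = 0.000129). BCAT1 was higher by 8.53 ± 0.18, the mitochondrial transhydrogenase NNT by 8.56 ± 0.20, BMP2 by 8.46 ± 0.47 and DENND2D by 8.30 ± 0.21. OR51F1 was higher by 9.42 ± 0.24, with 7 counts in the first LNCaP siControl library and 0 in the second, and by a fitted 14.38, which is no bound, without the first. SLC25A43, with 1 count in LNCaP, was higher by a fitted ratio of 585 (95% counting interval 129 to 28371). ETV1 was lower at -10.71 ± 0.23 and the peroxidase PXDN at -10.66 ± 0.19. CBLN2 and KLHL1, with 1 count each in abl, were lower by fitted ratios of 2481 (95% counting interval 555 to 122038) and 1458 (322 to 70967), and BMPR1B, with 2 counts, by 1164 (357 to 10660). DIRAS1 had 0 counts in abl and was at least 499-fold lower.

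All 22 stress response genes were higher in abl (22 adjusted over the list alone), with CHAC1 up by 4.81 ± 0.13 and the stress factor DDIT3 by 3.19 ± 0.12. Their median was 1.83 (camera adjusted p = 2.17e-26, and adjusted p = 0.0364 with an estimated correlation). Mitosis genes were higher for 29 of 34 and lower for 0 (29 and 0 adjusted over the list alone), with BUB1 up by 1.96 ± 0.13. Their median was 1.24 (camera adjusted p = 7.42e-06, adjusted p = 0.975 with an estimated correlation). The other 17 lists did not pass camera. Androgen response genes were 8 higher and 13 lower of 32, with KLK3 at -7.84 ± 0.38 and MAF at -4.95 ± 0.25. The CREB/cAMP-responsive list had 12 and 10 of 32, with the phosphodiesterase PDE10A at -8.33 ± 0.17, and neuroendocrine genes 5 and 4 of 13, with the adhesion molecule NCAM1 at 6.41 ± 0.25 and the tubulin TUBB3 at -6.37 ± 0.21. The CREB/ATF family had 10 and 5 of 21, apoptosis regulators 11 and 7 of 25 and p53 targets 9 and 5 of 21. Interferon genes had 7 and 7 of 26, and DNA repair 12 and 8 of 30. Cholesterol synthesis had 7 and 6 of 24, mesenchymal genes 3 and 8 of 17, fibroblast markers 0 and 2 of 6, and blood and endothelial markers 2 and 1 of 5. These counts were the same adjusted over the list alone, as were those of basal genes, 2 and 1 of 9, whose median of -0.64 (0 with genes at 0 set to their bounds) had an upward camera direction.

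Counts differed slightly adjusted over the list alone for DNA replication (7 and 14 of 38, against 7 and 13), luminal identity (7 and 8 of 18, against 8 and 8), fatty acid synthesis (9 and 5 of 18, against 9 and 6) and hypoxia and glycolysis (10 and 10 of 23, against 11 and 10). In all, 9896 genes differed, 4749 higher and 5147 lower in abl (4343 and 4340 with a stricter filter on low counts), with 1691 higher and 2008 lower by at least 1 on the log2 scale. Fry called 11 lists. Cell line, medium history and passage number cannot be told apart in this comparison.

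CREB1 binding was compared between the lines and with FOXA1 binding from the authors' peak lists on hg19, with 1 list per factor and line and so no replicate check. CREB1 had 27629 peaks in abl and 21991 in LNCaP, and FOXA1 had 79242 in abl. CREB1 peaks were largely shared between lines: 18433 abl peaks (66.7%, 95% Wilson interval 66.2 to 67.3) overlapped an LNCaP peak, against 2.22% after random shifts. In the other direction 18600 LNCaP peaks (84.6%, 84.1 to 85.1) overlapped an abl peak, against 2.80%. Of the abl CREB1 peaks, 13181 (47.7%, 47.1 to 48.3) overlapped a FOXA1 peak, against 4.72% after random shifts. Of the FOXA1 peaks, 13246 (16.7%, 16.5 to 17.0) overlapped a CREB1 peak, against 1.66%. Both FOXA1 shares depended on the rule: they were 28.4% and 9.9% with centres within 100 bp, and 21.9% and 7.6% among the peaks above the median score of each list.

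FOXA1 overlap differed with the sharing of CREB1 peaks between lines. It was 42.2% (95% Wilson interval 41.5 to 42.9) for abl CREB1 peaks also found in LNCaP and 58.8% (57.8 to 59.8) for those not found there. In 5 groups of near equal size by the authors' score, from lowest to highest, FOXA1 overlap of abl CREB1 peaks was 57.5%, 58.2%, 52.4%, 35.9% and 34.5%, whereas overlap with LNCaP CREB1 peaks was 24.3%, 41.7%, 72.1%, 95.8% and 99.7%. Median scores were 353 for shared and 111 for unshared peaks, and no test held the score fixed. For LNCaP CREB1 peaks, overlap with the abl FOXA1 peaks was 41.2% (40.5 to 41.9) for those shared with abl and 43.1% (41.4 to 44.7) for the others, with median scores of 249 and 101. No FOXA1 list of LNCaP was analysed here, so FOXA1 sites found only in LNCaP could not count. Both CREB1 lists had the same highest score, 3233.06, and both held a peak at 3230.05, so the highest scores may not order peaks. By this score, the highest abl CREB1 peak lay on chromosome 12 from 132628351 to 132629434. It overlapped an LNCaP CREB1 peak but no FOXA1 peak. The next, on chromosome 11 from 2421168 to 2422298 and on chromosome 3 from 156892344 to 156893373, overlapped both. The highest FOXA1 peak, on chromosome 10 from 113339054 to 113340154, overlapped an abl CREB1 peak but no LNCaP one. The other top FOXA1 peaks, on chromosome 3 from 188556679 to 188557513 and on chromosome 1 from 121483843 to 121485512, overlapped both CREB1 lists. In LNCaP, the CREB1 peaks on chromosome 1 from 564402 to 570372 and on chromosome 20 from 32398601 to 32399348 tied for the highest score. The former was 5971 bp wide and found in every list. Peaks were not filtered here for regions prone to mapping artifacts, so peaks found in every list need not mark shared binding. The latter and the next LNCaP peak, on chromosome 1 from 9488649 to 9489586, were shared with abl CREB1 but not with abl FOXA1.

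**Figure D5:**
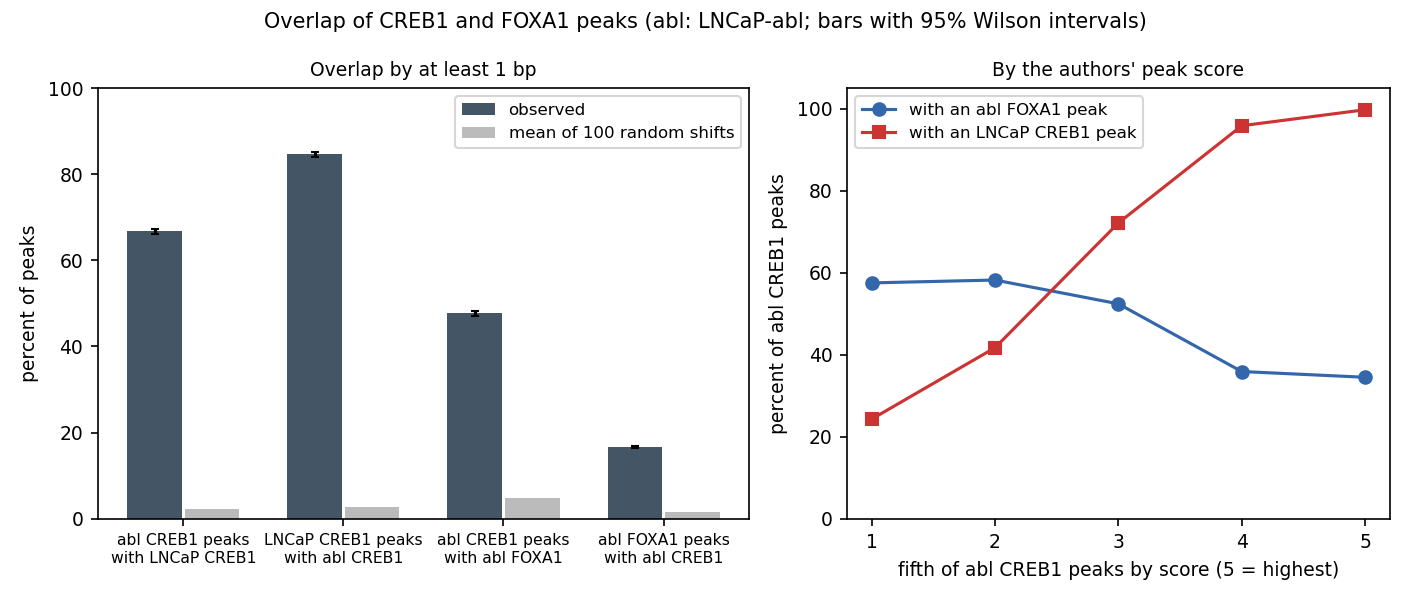
Left, percent of peaks that overlap another list by at least 1 bp (dark bars with 95% Wilson intervals) and the mean of 100 random shifts (grey bars). Right, percent of abl CREB1 peaks that overlap an abl FOXA1 peak or an LNCaP CREB1 peak, in 5 groups by the authors' score, with FOXA1 overlap going from 57.5% to 34.5% and LNCaP overlap from 24.3% to 99.7%.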

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

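The tests of a single deviating library, of NF-kappaB targets in LNCaP under siFOXA1 alone, of the number of siRNAs per target, of the siControl cultures of abl and of white blood cell markers near 0 under the knockdowns were chosen only after the result was seen. The NF-kappaB, tRNA synthetase and white blood cell lists were made after the main results were seen. For them, beforehand means before the list itself was tested. All the differences below stand out because edgeR's quasi-likelihood test of the difference between the lines' knockdown effects, or camera over a gene list, passed at a Benjamini-Hochberg adjusted p below 0.05. The siCREB1 effect differed between abl and LNCaP for 3969 genes and the siFOXA1 effect for 5068 genes. The knockdowns also differed in strength. Of the siControl level, 56.9% of CREB1 was left under siCREB1 in abl and 41.2% in LNCaP. For FOXA1 under siFOXA1 it was 40% and 28.5%, and no test held this fixed.

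Differences in the siCREB1 effect are given as the abl log2 change minus the LNCaP one. They were -3.70 ± 0.19 for CHAC1 (edgeR adjusted p = 2.8e-08), -3.60 ± 0.15 for FAM129A, -4.40 ± 0.26 for LOC100505633 and -5.56 ± 0.57 for S100P. For genes of dividing cells they were 3.10 ± 0.33 for DLGAP5, 3.01 ± 0.27 for MYBL2, a cell cycle transcription factor, and 3.69 ± 0.29 for RRM2 (edgeR adjusted p = 1.32e-06). The value of 5.27 ± 1.33 for DENND2D (edgeR adjusted p = 0.0112) is a fitted one and no bound, since LNCaP siCREB1 had 0 counts and the siControl libraries 3 each.

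For siFOXA1 the difference for THBS1 was -9.13 ± 0.29 (edgeR adjusted p = 3.28e-10), since it fell in abl and rose in LNCaP. The complement regulator CD55 differed by -4.40 ± 0.36 and LRRTM1 by -4.17 ± 0.83, whereas MSN at -4.89 ± 0.97 was at -2.25 (adjusted p = 0.445) without the first abl siControl library. Positive differences were 3.90 ± 0.18 for ABP1 (edgeR adjusted p = 5.3e-09), 3.73 ± 0.20 for ACPP, 3.64 ± 0.44 for the glutathione transferase GSTA1 and 3.91 ± 0.39 for OR51E1.

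By list, 21 of 22 stress response genes had a lower siCREB1 effect in abl (21 adjusted over the list alone). Their median difference was -1.18 (camera adjusted p = 4.16e-55, and adjusted p = 0.00423 with an estimated correlation). Mitosis genes had a higher one for 31 of 34 (34 adjusted over the list alone; median 1.58) and DNA replication genes for 25 of 38 (29; median 0.97). Interferon genes had a lower one for 18 of 26 (20 adjusted over the list alone; median -1.35). Medians of the other lists past camera were 0.51 for androgen response, -0.13 for the CREB/ATF family, 0.29 for DNA repair and 0.05 for CREB/cAMP-responsive genes, whose camera direction was downward. Apart from the stress response, camera passed none of these with an estimated correlation (adjusted p = 0.0594 for the CREB/ATF family to adjusted p = 0.277).

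For the siFOXA1 effect, 21 of 22 stress response genes were again lower in abl (21 adjusted over the list alone). The median difference was -1.49 (camera adjusted p = 2.67e-51, and adjusted p = 0.00561 with an estimated correlation). Mitosis genes were lower for 33 of 34 (34 adjusted over the list alone; median -1.51) and interferon genes for 18 of 26 (20; median -1.65). Fatty acid synthesis was higher for 13 of 18 (14 adjusted over the list alone; median 0.65) and cholesterol synthesis for 15 of 24 (16; median 0.53). Other medians were -0.30 for DNA replication, -0.54 for CREB/cAMP-responsive genes, -0.15 for the CREB/ATF family, -0.29 for p53 targets, 0.26 for hypoxia and glycolysis and -0.37 for DNA repair. Apart from the stress response, camera passed none of these with an estimated correlation (adjusted p = 0.09 for the CREB/ATF family to adjusted p = 0.507).

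Interferon response genes rose in abl under siFOXA1 and in LNCaP under both knockdowns, though camera with an estimated correlation passed none of these (adjusted p = 0.377, 0.143 and 0.104). A single deviating library is argued against, since the lowest median with any library left out was 1.27. Sensing of double-stranded siRNA could also switch on NF-kappaB targets. By the bound set beforehand, a median below its lower limit in any of the 3 comparisons would speak against such sensing in all 3. The median lay below it in LNCaP under siCREB1 (-0.13, 2 higher and 1 lower of 11) and in abl under siFOXA1 (0.17, 2 higher and 0 lower of 11). Few members were called, and the rule as run also asked for an upper quartile below that limit, which neither comparison met. The test therefore decides nothing, and sensing that leaves these targets unchanged stays open. The siControl cells received siRNA at the same dose, so sensing common to all siRNAs would cancel in these comparisons. In LNCaP under siFOXA1 alone the median of NF-kappaB targets was 0.55, with 6 of 11 higher (camera adjusted p = 0.019, adjusted p = 0.358 with an estimated correlation). Sensing that switches them on would give such a rise there. Loss of the targeted factor cannot be told apart from an effect of its siRNA, since the labels give 1 siRNA label per target.

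Stress response genes fell in abl under both knockdowns. A single deviating siControl library is argued against, since the higher median with either siControl library left out was -1.27. Lower activity of the ATF4 program may account for it: the cytosolic tRNA synthetases, many of which ATF4 induces, had medians of -0.65 and -0.57 (camera adjusted p = 0.102 and 0.126 with an estimated correlation). A stressed state of the abl siControl cultures stays open, since abl stood 1.83 above LNCaP siControl under siControl but 0.37 and 0.18 under siCREB1 and siFOXA1. These medians cannot be told apart from an effect of the knockdowns, because no untreated abl group was analysed here.

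White blood cell transcripts appeared in the first siControl library of both lines. Over all 25 markers, the test set beforehand, the lower ratio of the first to the second library was 1.04, the larger Poisson p 0.023 and the higher ratio of the second siControl library to the knockdowns 0.921, which alone would speak against white blood cells, but that test is void, since LCP1, which the lines express, held 4795 of 5269 counts in LNCaP and 18391 of 18994 in abl. Over the 10 markers with at most 2 counts in every knockdown library, the first and second libraries held 24 and 2 counts in LNCaP and 40 and 0 in abl. Scaled by depth, with the second library set to a floor of 3 counts, the first stood 4.41 and 3.25 times higher. The larger one-sided Poisson p was 0.000181, but it takes the first library's count as exact and so is too small. Without the floor, the lower 95% counting limits of the ratio were 1.64 in LNCaP and 2.52 in abl, which argues against deeper sequencing. These limits cover the counting error of both libraries only. An effect of the control siRNA, which both libraries received, is argued against as well (lower 95% counting limit of the ratio 1.64, and 35 and 2 of 10000 gene sets matched on siControl counts with as many counts in the first library). RNA or reads from white blood cells cannot be told apart from other causes. The ratios of 4.41 and 3.25 lie short of the bound of 5. Both were set by the floor of 3 counts, which the second libraries did not reach, so that bound could not be met and decides nothing.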

How the results depend on the processing

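Only the fit without both first siControl libraries and the crossed block were chosen after the data were seen. Of 115 counts of changed genes under alternatives, 114 were within 1.5 times the reported count. The exception was genes called under both knockdowns in LNCaP, 2006 at an adjusted p below 0.01 against 3338, a stricter threshold by construction. With each library left out in turn, counts ranged from 6436 to 6870 and 7231 to 7906 for siCREB1 and siFOXA1 in abl, 4326 to 5000 and 5818 to 7051 in LNCaP, and 8306 to 9551 for abl against LNCaP. Without both first siControl libraries they were 6786, 7606, 4980, 6813 and 7774. DESeq2 gave 6922, 7774, 4903, 6630 and 8967. Where a group kept 1 library, it was assumed to vary like the other groups.

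With the replicate number as a block, counts were 8054, 8817, 5975, 7792 and 9923. Deviations of same-numbered libraries correlated at -0.16, -0.13 and 0.30 in LNCaP, at 0.11, 0.11 and 0.36 in abl, and at 0.46 between the siControls of both lines. With 2 numbers per group and no shared batch in the labels, they were not taken as pairing. A crossed block in LNCaP gave 6345 and 8093. The block ended the call of KRT14 in abl under siFOXA1 and of DIRAS1 between the knockdowns in abl, and camera's call of the neuroendocrine list in LNCaP under siCREB1 (adjusted p = 0.0561). It changed no other call of a named gene, or of a fixed list in these 5 comparisons.

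Camera called 6, 8, 7, 6 and 2 lists for siCREB1 and siFOXA1 in abl, the same in LNCaP, and abl against LNCaP. With an estimated correlation it called 2, 2, 1, 0 and 1, and fry, which does not compare a list with other genes, called 9, 13, 12, 12 and 11.

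Of 3023 alternatives for 266 named gene results, 2943 kept direction and call, 76 lost the call, 1 gained it and 3 reversed. FOXA1 in abl under siCREB1 ranged from -0.05 to 0.11 with a library left out. PTPRC, a leukocyte gene called lower in LNCaP under siFOXA1, had 0 counts there, so its fitted values are no bounds. They ranged from -6.01 to 0, and the value was at 0 without both first siControl libraries, since its siControl counts lie in the first library. For FOXA1 the cause was not tested.

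Peak overlap moved with the rule. With at least 50% of both peaks shared, centres within 100 bp, peaks within 1 kb and only the peaks above the median score of each list, it was 64.6%, 56.1%, 68.2% and 74.1% of abl CREB1 peaks with LNCaP. It was 81.2%, 70.5%, 85.5% and 93.5% of LNCaP CREB1 peaks with abl. It was 37.4%, 28.4%, 53.7% and 21.9% of abl CREB1 peaks with FOXA1, and 13.0%, 9.9%, 19.6% and 7.6% of FOXA1 peaks with CREB1. The first 3 rules differ by construction. The last does so in part, since it shortens both lists, and any further cause was not tested. Peaks near promoters and responses of genes near peaks, with their distance alternatives, were not run. Depth limits genes with few counts, above all against the second abl siControl library of 9092597 reads.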

Other observations

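The gene lists in this part were chosen only after the main results were seen, except that the fall of tRNA synthetases was written down before it was tested. Genes that load peptides onto HLA class I for display to T cells rose in LNCaP under both knockdowns. Of 15 measured members, 13 rose and 0 fell under siCREB1, with a median log2 change of 0.81 (camera adjusted p = 1.43e-06, adjusted p = 0.492 with an estimated correlation). Under siFOXA1, 14 rose and 0 fell, with a median of 1.52 (camera adjusted p = 6.61e-14, adjusted p = 0.116 with an estimated correlation). The heavy chain gene HLA-B rose by 0.93 ± 0.14 under siCREB1 and 1.94 ± 0.15 under siFOXA1, its partner B2M by 0.98 ± 0.16 and 1.66 ± 0.16, and the peptide transporter TAP1 by 0.56 ± 0.11 and 1.42 ± 0.11. HLA genes share reads with close relatives, so single values are uncertain. In abl, 4 rose and 1 fell under siCREB1 (camera adjusted p = 0.458), and 6 rose and 2 fell under siFOXA1 (camera adjusted p = 0.14). Whether these effects differ between the lines was not tested.

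Cytosolic and mitochondrial tRNA synthetases, which charge tRNAs with amino acids, were tested as separate lists and not against each other. The knockdown values given here for these lists and their members are for abl. Of 20 cytosolic members, 12 fell and 5 rose in abl under siCREB1, with a median of -0.65 (camera adjusted p = 5.3e-12, adjusted p = 0.102 with an estimated correlation). In abl under siFOXA1, 11 fell and 6 rose, with a median of -0.57 (camera adjusted p = 3.13e-11, adjusted p = 0.126 with an estimated correlation). WARS fell by 1.88 ± 0.06 and 2.02 ± 0.06 under siCREB1 and siFOXA1, and GARS by 1.78 ± 0.07 and 2.22 ± 0.07. Of 17 mitochondrial members, 13 rose and 0 fell in abl under siCREB1, with a median of 0.36 (camera adjusted p = 0.000326, adjusted p = 0.176 with an estimated correlation). In abl under siFOXA1, 10 rose and 1 fell (median 0.37, camera adjusted p = 0.108). Under siControl, 17 of 20 cytosolic members were higher in abl than in LNCaP, with a median of 0.93 (camera adjusted p = 1.04e-13, adjusted p = 0.077 with an estimated correlation), whereas the mitochondrial list, with 3 higher and 10 lower of 17, did not pass (camera adjusted p = 0.45). In LNCaP neither list passed camera under either knockdown.

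The rise of ID1 and ID3, known targets of BMP signalling, led to a test of 13 other BMP pathway genes, which was negative. Their medians were 0.68 and 0.17 under siCREB1 and siFOXA1 in abl and 0.73 and 0.05 in LNCaP (camera adjusted p = 0.458, 0.449, 0.43 and 0.978). Among genes of interferons themselves, 3 of 3 measured rose in LNCaP under siFOXA1, with too few siControl counts for a fold (camera adjusted p = 0.019, adjusted p = 0.129 with an estimated correlation). In LNCaP under siCREB1, 0 of 3 were called (camera adjusted p = 0.963), and in abl under siFOXA1 1 of 3 was higher (camera adjusted p = 0.879).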
